A study of Homo sapiens with 8 samples.

How the data were processed

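Ribosome footprints were measured in 8 libraries of BJ-HRAS fibroblasts, 2 clones per genotype, each without and with 7 days of 100 nM 4-OHT. The values are in 2 tables, one without 4-OHT (11546 genes) and one with it (11079 genes), with 10685 genes in both. The deposited values are RPKM as read from the numbers themselves, since the tables name no unit. Each value multiplied by the span of its gene from start to end, introns included, summed to nearly the same total in every library, as RPKM over that span would. The authors named the aligner STAR and the genome GRCh38 in the processing notes, and the labels name the ribosome profiling protocols of McGlincy and Ingolia. Version numbers, the read counter, the annotation and the handling of reads that map to several places are not given in the sources used here.

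Low values multiplied by the span came in whole multiples of one step per library, with between 77.5% and 82.9% of them within 0.1 of a whole number of reads. The step gave an estimate of the reads behind each value and of the depth of each library. The step was chosen to give this agreement, and some values lie near a whole number by chance. Values that were not near one may come from a span other than the matched one. Recovered reads of single genes are therefore approximate, and so are the read filter and tests that rest on them. Spans came from the RefSeq annotation of GRCh38.p14, by gene identifier for 11345 of 11546 and 10884 of 11079 genes, then by symbol or older symbol; 102 and 101 genes without a span were left out of recovered reads and of the tests. No per-sample column was left unused. Floors are the value that 3 reads would give in a library and cover counting error only, since reads copied by PCR are not independent molecules.

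The tests, the gene lists, the rule for named genes and the alternatives in the closing section not described as later were chosen before the data were examined. A test on read counts had been planned, with limma-trend on log2(value + 1) within each table if the values proved to be normalised. They did, so limma-trend was the test. The added 1 exceeded the median value of every library (0.535 to 0.727 RPKM). It shrinks log2 fold changes, most of all for low values. Log2 fold changes and list medians by limma-trend are therefore smaller than the ratios of the RPKM values printed beside them. Knockout and WT clones were compared within each table on the 4 libraries of that table, which left 2 residual degrees of freedom. The change with 4-OHT in WT clones, in knockout clones and the difference of both (interaction) were fitted on all 8 libraries over the shared genes. 4-OHT and the table, with any batch of its libraries, cannot be told apart, and neither can the genotype and the clones that carry it. Each clone counted as 1 replicate. A gene was tested with at least 10 recovered reads in at least 2 libraries, and p-values were adjusted by Benjamini-Hochberg with a threshold of 0.05 and no minimum fold. With 2 libraries against 2, an exact permutation test has 3 distinct splits and can give no p below 1 in 3, so single values were given without one.

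Of 28 gene lists, those with at least 5 tested genes were tested with camera, which compares the genes of a list with all other tested genes, at a preset correlation between genes of 0.01. The other 6 lists were described and not tested. Adjustment was over the lists of 1 comparison. Beside this test stand the number of called genes over all genes, the number adjusted over the list alone, and camera with an estimated correlation. Medians of lists in the 4-OHT comparisons were also set against 10000 random lists matched on gene span, a check chosen after the tables were seen.

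Named genes included a fixed panel, among them SNORA13, EPB41L4A-AS1, EPB41L4A, HRAS, RPL23, RPL5, RPL11, MDM2, CDKN1A, CDKN2A, LMNB1, MKI67, IL6, CXCL8 and DKC1. Added to it were, per comparison, the 8 genes with the largest rise and the 8 with the largest fall among those called, with a mean of at least 10 CPM and clones of the groups that did not overlap. From each list with called genes up to 4 with the largest change were added, and where no gene was called the 4 genes with the smallest p. For the comparisons with no called gene the same rule was also applied to limma-voom calls, a choice made after the tables were seen. The text gives values for part of the genes so chosen and counts for the rest, and not every list is described.

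Alternatives were a pseudocount of 0.1, no filter, no ribosomal protein and mitochondrially encoded genes, all 8 libraries or only the 4 of the comparison in the fit, each library left out in turn, and the clone as a block (replicate block), fixed for 4-OHT and random with limma-voom between genotypes. Chosen after the tables were seen were limma-voom on recovered reads without a block and, for 4-OHT, with the clone as a fixed block, limma-trend with the clone as a random block, median-ratio scaling, and log2(CPM + 1), that is without division by span. Several alternatives are close variants of one another, and libraries were left out with limma-trend only. The number of alternatives a gene passed is therefore not a number of independent checks. The labels give each clone number both without and with 4-OHT. The differences between the 2 clones of a genotype without and with 4-OHT correlated across 8715 genes with an r of 0.148 in WT and 0.00690 in knockout clones, and genes are not independent replicates. The clone was not a block in the tests given first, as fixed in the design.

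The tests were tried on simulated reads at these depths with 200 changed genes, 100 each by 2-fold and 4-fold, and a dispersion of 0.02. Without 4-OHT, limma-trend recovered 10% of the 2-fold and 83% of the 4-fold changes between genotypes, and limma-voom 45% and 91%. With 4-OHT these were 0% and 26%, and 37% and 81%. For 4-OHT in WT clones limma-trend recovered 5% and 60% and limma-voom 32% and 92%, in knockout clones 10% and 72% and 46% and 86%, and for the interaction 0% and 10% and 4% and 60%. At most 10 unchanged genes were called in any of these runs. R 4.3.3 with limma 3.58.1 and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 were used.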

Results

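Ribosome profiling, which sequences the stretches of mRNA covered by translating ribosomes, was analysed in 8 libraries of BJ cells, an established line of human skin fibroblasts. The labels give all cells as BJ-HRAS. HRAS is a signalling GTPase whose oncogenic form drives fibroblasts into senescence, a lasting arrest of growth. 4-hydroxytamoxifen (4-OHT) is the ligand commonly used to switch on proteins fused to a modified estrogen receptor domain. The cells were wild-type (WT, clones 15 and 54) or knocked out for SNORA13 (clones 66 and 69), a small nucleolar RNA, a class of RNAs that guide chemical modification of ribosomal RNA. Each clone was collected without 4-OHT and after 7 days of 100 nM 4-OHT, which gave 4 groups of 2 libraries.

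The values were footprint RPKM, and approximate read numbers behind them were recovered from the values. The WT libraries without 4-OHT held 1321941 (clone 15) and 790753 (clone 54) reads, and the knockout libraries without 4-OHT held 901951 (clone 66) and 1710474 (clone 69). With 4-OHT, the WT libraries held 1686598 (clone 15) and 589011 (clone 54) reads. The knockout libraries with 4-OHT held 190878 (clone 66) and 982085 (clone 69). The knockout library of clone 66 with 4-OHT was the shallowest, with 3169 of 11079 listed genes at 0. RNA abundance in the same cells was not analysed here, so a footprint value reflects the amount of an mRNA and its translation together. SNORA13 itself, its host gene EPB41L4A-AS1, HRAS, CDKN2A and LMNB1 were not found under these names in either table. The knockout was therefore not checked on these values.

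Genes of the fibroblast matrix list took between 15.3% and 17.1% of the reads of each library without 4-OHT and between 2.74% and 3.18% with 4-OHT. Marker lists of other cell types took small shares. Leukocyte markers held between 0.0149% and 0.0406% of a library's reads, epithelial markers between 0.0111% and 0.0381%, and melanocyte markers between 0.00134% and 0.00786%. Keratinocyte markers held between 0.00228% and 0.00700%. Endothelial markers held at most 8.76e-04% of the reads of a library without 4-OHT and between 0.00103% and 0.00553% with it.

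The first comparison asked how WT clones respond to 4-OHT. Most tested genes of RAS-ERK output, ribosomal proteins, histones and the mitochondrial genome rose, most of the fibroblast matrix and interferon response lists fell, and secretory factors moved in both directions. With an estimated correlation between genes no list kept its call (lowest adjusted p 0.0662). STC1, a secreted glycoprotein hormone, rose from 2.48 ± 0.314 to 366 ± 75.8 RPKM (mean ± SD, n = 2 clones), and MMP1 (ENSG00000196611.5; chromosome 11, 102789919 to 102798160), a collagen-degrading protease, from 12.5 ± 4.65 to 1415 ± 4.23. CDKN1A (ENSG00000124762.13; GRCh38.p14 chromosome 6, 36676463 to 36687332), the cell-cycle inhibitor p21, rose from 10.01 ± 5.90 to 151 ± 30.4, a log2 fold change of 3.88 ± 0.42 (SE). COL1A1 (ENSG00000108821.13; chromosome 17, 50184101 to 50201631), a chain of type I collagen, fell from 1646 ± 74.05 to 83.1 ± 8.60. Of 8715 genes tested with limma-trend, 1191 were higher and 709 lower with 4-OHT at an adjusted p under 0.05.

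Of 19 tested senescence-associated secretory factors, 12 rose and 5 fell (13 and 5 adjusted over the list alone). The list test gave an adjusted p of 0.00309, and an adjusted p of 0.193 with an estimated correlation. CXCL8, the neutrophil chemokine interleukin-8, rose from 0.961 ± 1.36 to 119 ± 4.58 RPKM, and the cytokine IL1B from 1.20 ± 0.696 to 109.7 ± 36.2. IGFBP3, an insulin-like growth factor binding protein counted in this list, fell from 189 ± 12.8 to 3.05 ± 1.53. Of 19 RAS-ERK output genes, 17 rose and 1 fell, over all genes and adjusted over the list alone alike (list adjusted p = 1.28e-09, adjusted p = 0.0662 with an estimated correlation). PHLDA1 rose from 5.68 ± 1.92 to 131 ± 41.5 RPKM and DUSP4, a phosphatase that switches off ERK, from 0.673 ± 0.140 to 25.04 ± 3.15. TMEM158, a membrane protein known to be induced by RAS, rose from 7.52 ± 1.20 to 884 ± 231. Of 11 senescence hallmark genes, 7 rose and 1 fell (8 and 2 adjusted over the list alone, list adjusted p = 0.00309, adjusted p = 0.173 with an estimated correlation). Among them HMGA1, a chromatin protein of senescence-associated foci, rose from 2.08 ± 0.263 to 153 ± 36.1 RPKM, and CDKN2B, the cell-cycle inhibitor p15, from 0.887 ± 0.416 to 5.78 ± 3.46. By limma-voom HMGB1 and HMGB2 were higher too, and GLB1 and MKI67 lower. The list holds cell-cycle inhibitors beside the proliferation marker MKI67, so a count of rises does not measure senescence.

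Of 28 fibroblast matrix genes, 1 rose and 21 fell, over all genes and adjusted over the list alone alike (list adjusted p = 1.55e-17, adjusted p = 0.0662 with an estimated correlation). The proteoglycan DCN fell from 42.8 ± 6.51 to 1.16 ± 0.338 RPKM and COL3A1 from 105 ± 1.91 to 4.70 ± 0.528. Of 23 interferon response genes, 17 fell and 0 rose (19 and 0 adjusted over the list alone, list adjusted p = 2.43e-14, adjusted p = 0.155 with an estimated correlation). IFI6 fell from 839 ± 345 to 23.7 ± 7.23 RPKM and IFIT1 from 36.4 ± 5.01 to 1.48 ± 0.0192. Lysosome genes fell more often than they rose, with 9 of 29 lower and 2 higher (11 and 2 adjusted over the list alone, list adjusted p = 2.73e-04, adjusted p = 0.205 with an estimated correlation). The protease CTSD fell from 77.00 ± 19.5 to 32.2 ± 8.21 RPKM, and the protease CTSL rose from 107 ± 17.98 to 251 ± 1.84. CTSD passed in 9 of 13 alternatives. The largest falls outside these lists included SYPL2, from 63.95 ± 3.02 to 0.514 ± 0.351, and ADAMTS1, a secreted metalloprotease, from 273 ± 11.8 to 8.02 ± 2.38.

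Of 32 large-subunit (60S) ribosomal protein genes, 26 rose and 1 fell (28 and 1 adjusted over the list alone, list adjusted p = 5.19e-12, adjusted p = 0.0662 with an estimated correlation). Of 21 small-subunit (40S) genes, 16 rose and 0 fell (19 and 0 adjusted over the list alone, list adjusted p = 3.19e-09, adjusted p = 0.0662 with an estimated correlation). RPL23 rose from 7.74 ± 0.896 to 27.4 ± 0.345 RPKM, RPL11 from 48.9 ± 6.60 to 134 ± 5.63 and RPL5 from 5.70 ± 0.329 to 15.9 ± 0.440. Free forms of these proteins are known to bind MDM2, a ubiquitin ligase, and the spans of RPL23 and RPL5 hold snoRNA genes. Values of the other genes in this paragraph, DKC1 among them, are over spans with introns too, so a like limit may apply. Among 60S assembly factors 15 of 41 rose and 0 fell (17 and 0 adjusted over the list alone, list adjusted p = 7.70e-04, adjusted p = 0.155 with an estimated correlation), with NOP16 from 2.63 ± 1.59 to 12.5 ± 0.493. Among 40S assembly factors 9 of 43 rose and 0 fell, in both adjustments alike, that over all genes and that adjusted over the list alone (list adjusted p = 0.0170, adjusted p = 0.173 with an estimated correlation). Enzymes and core proteins of snoRNA-guided modification rose in 8 of 14 cases and fell in 0, also when adjusted over the list alone (list adjusted p = 0.00343, adjusted p = 0.193 with an estimated correlation). NOP10, a core protein of the H/ACA class of small nucleolar RNAs, rose from 52.2 ± 10.4 to 251 ± 8.21 RPKM, and DKC1, the pseudouridine synthase of that class, from 2.72 ± 0.340 to 5.01 ± 0.494. Of 29 translation factors, 10 rose and 0 fell (14 and 0 adjusted over the list alone, list adjusted p = 0.00314, adjusted p = 0.173 with an estimated correlation). The RNA polymerase I list did not pass its test (adjusted p = 0.431), with 2 genes higher and 2 lower, over all genes and adjusted over the list alone. UBTF, the nucleolar transcription factor of this polymerase, fell from 7.16 ± 0.650 to 2.87 ± 0.424 RPKM. Over 13 alternatives UBTF passed in 4 (highest adjusted p 0.208), and NOP16 and DKC1 passed in 6 each (highest 0.249 and 0.206). Reads of ribosomal protein and histone genes can be shared with near-identical copies and pseudogenes, so single members of these families are uncertain.

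Genes of mitosis rose in 9 of 33 cases and fell in 0 (9 and 1 adjusted over the list alone, list adjusted p = 0.00451, adjusted p = 0.235 with an estimated correlation). PTTG1, the separase inhibitor securin, rose from 3.58 ± 1.16 to 37.8 ± 11.1 RPKM and the mitotic cyclin CCNB1 from 6.88 ± 0.0953 to 22.8 ± 1.05. MKI67, the proliferation marker Ki-67, went from 2.80 ± 0.120 to 1.48 ± 0.0889 and missed the threshold (adjusted p = 0.0522). It passed as lower in 7 of 13 alternatives, limma-voom among them (adjusted p = 0.0183), and in 0 of 13 in knockout clones. DNA replication genes did not pass as a list (adjusted p = 0.440), and 2 of 30 rose (0 adjusted over the list alone). Replication-dependent histone genes rose in 36 of 39 cases and fell in 0 (37 and 0 adjusted over the list alone, list adjusted p = 1.55e-17, adjusted p = 0.173 with an estimated correlation), with HIST1H4D from 101 ± 29.4 to 1052 ± 120.2 RPKM. All 4 mitochondrially encoded genes tested, of 13 in the list, rose, too few for a list test. MT-ATP6 rose from 1.11 ± 1.57 to 383 ± 37.9 RPKM, and these genes together took 0.00223% and 8.70e-04% of the reads of the WT clones without 4-OHT and 0.119% and 0.0619% with it. Without 4-OHT MT-ATP6 lay under the floor of 3 reads in both WT clones, so the size of its rise is uncertain. Nuclear genes of oxidative phosphorylation (OXPHOS) rose in 16 of 24 cases and fell in 0 (19 and 0 adjusted over the list alone, list adjusted p = 3.58e-08, adjusted p = 0.0662 with an estimated correlation). Cholesterol synthesis genes rose in 13 of 20 cases and fell in 0 (15 and 0 adjusted over the list alone, list adjusted p = 7.34e-07, adjusted p = 0.0662 with an estimated correlation), with the sterol oxidase MSMO1 from 2.69 ± 0.686 to 17.8 ± 2.91 RPKM. Targets of the stress factor ATF4 (adjusted p = 0.136), cytosolic chaperones (0.166) and chaperones of the endoplasmic reticulum (0.695) did not pass their list tests. With fry, a rotation test of lists, cytosolic chaperones passed (adjusted p = 2.94e-04), with 6 of 16 genes higher and 1 lower.

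**Figure D1:**
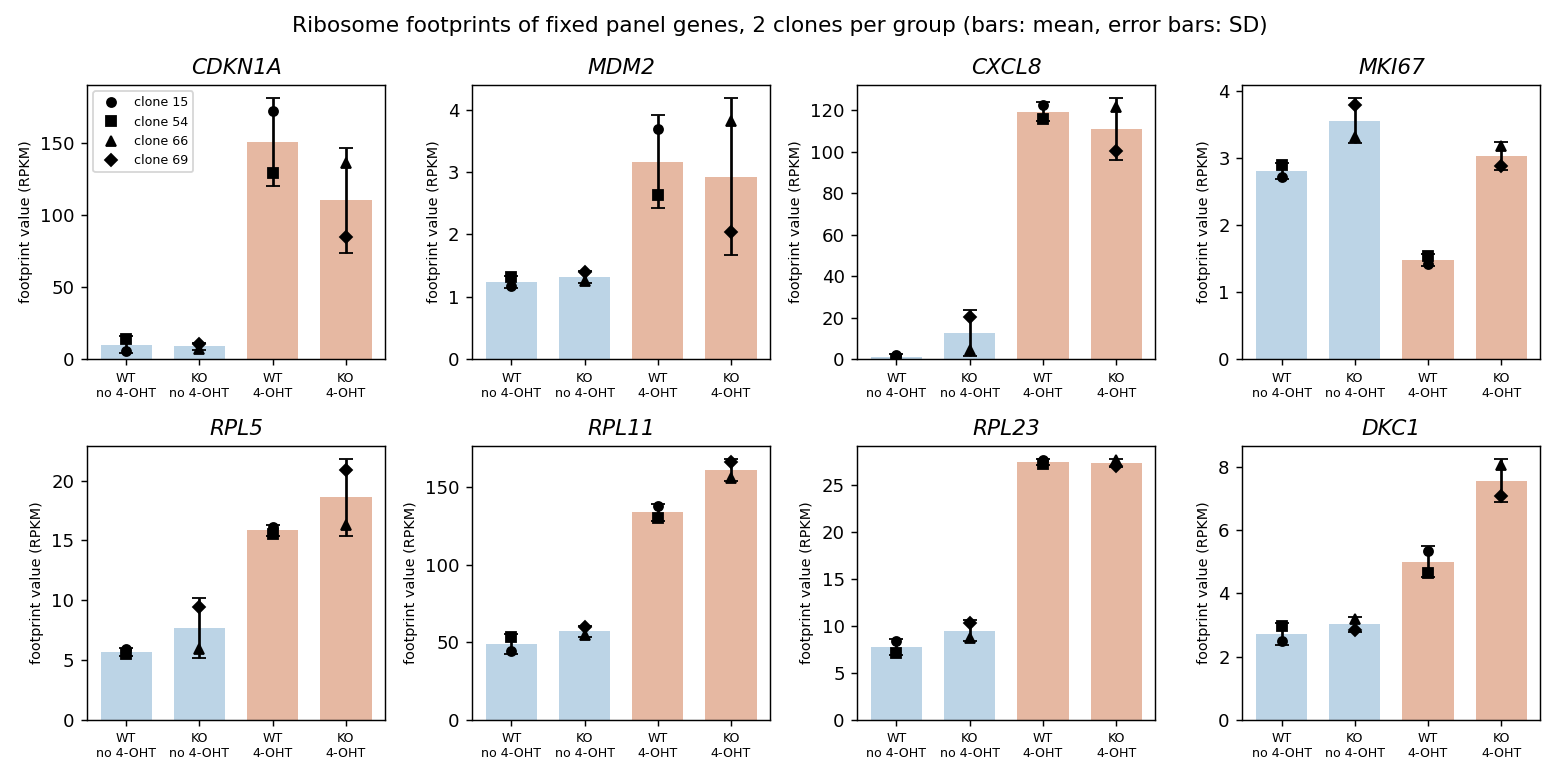
Footprint values (RPKM, linear axes from 0) of 8 genes of the fixed panel in the 4 groups; bars are means, error bars SD and symbols the 2 clones of each group. CDKN1A, CXCL8, RPL5, RPL11, RPL23 and DKC1 sit higher with 4-OHT than without in every clone, while MKI67 with 4-OHT is 1.48 ± 0.0889 RPKM in WT and 3.02 ± 0.208 in knockout clones.

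Values with 4-OHT and without came from separate tables, normalised per library, and 4-OHT cannot be told apart from any batch of the tables. Genes with a short genomic span were higher with 4-OHT (Spearman rho of span and log2 fold change -0.282 across genes, which are not independent replicates), a trend that moves with the histone, ribosomal protein, OXPHOS and mitochondrially encoded lists. The median log2 fold change of both ribosomal protein lists and the OXPHOS list still lay above the central 95% of 10000 random lists matched on span. For 60S ribosomal proteins it was 1.43 against 0.07 to 0.80. The 40S assembly factors, which passed their list test, lay inside their range (0.30 against -0.03 to 0.33). The histone median was 2.15 against 0.61 to 1.31, but with a median span of 494 bp this list could not be matched closely. Only 60 tested genes, histones among them, had a span up to 1000 bp, so its random lists drew mostly on longer genes. That range therefore does not part histones from the span trend. The random draws also took genes as independent. Over all genes the median log2 fold change was 0.06 as deposited, -0.02 with median-ratio scaling and 0.22 with limma-voom; median-ratio scaling gave 824 genes higher and 981 lower in place of 1191 and 709, and no gene with a call in both had the opposite sign. Leaving out 1 library gave 870 genes without WT clone 15 and 815 without WT clone 54 of the libraries without 4-OHT, and 1080 without clone 15 and 823 without clone 54 of those with it. Of 101 genes chosen by the rule for named genes and called here, 20, 27, 14 and 26 were not called in these 4 settings, and 0 changed sign.

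In the knockout clones, the question was whether the same response to 4-OHT was seen. Most tested genes of RAS-ERK output, ribosomal proteins and histones rose here too, most matrix and interferon response genes fell, and secretory factors again moved in both directions. No list kept its call with an estimated correlation (lowest adjusted p 0.0925). Of 8715 genes, 1504 were higher and 929 lower with 4-OHT. MMP1 rose from 12.99 ± 13.2 to 2278 ± 91.5 RPKM (mean ± SD, n = 2 clones), STC1 from 3.50 ± 1.41 to 519 ± 48.8, and CDKN1A from 8.73 ± 2.40 to 110.1 ± 36.4, a log2 fold change of 3.50 ± 0.42 (SE). Of the genes higher in WT clones, 935 were also higher in knockout clones, where independent lists would share 205.5. Of those lower, 548 were shared, where independent lists would share 75.6, and 2 genes passed in opposite directions, ACSS1 (lower in WT and higher in knockout clones) and ZNF524 (higher in WT and lower in knockout clones). The log2 fold changes of both comparisons, which share no library, correlated across genes with a Pearson r of 0.872 and a Spearman rho of 0.786. Both comparisons came from one fit with a shared variance per gene, and both carry any batch of the tables and the span trend. An overlap or correlation above that of independent lists therefore does not by itself show a shared response to 4-OHT.

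Of 19 secretory factors, 12 rose and 6 fell (13 and 6 adjusted over the list alone, list adjusted p = 0.0186, adjusted p = 0.271 with an estimated correlation). Without knockout clone 69 with 4-OHT this list missed the threshold (adjusted p = 0.0575), and so it did with only the 4 knockout libraries in the fit (0.0621). CXCL8 rose from 12.4 ± 11.1 to 111 ± 15.00 RPKM, IGFBP3 fell from 194 ± 1.24 to 0.620 ± 0.877 and the chemokine CCL2 fell from 79.2 ± 26.3 to 0.531 ± 0.750. RAS-ERK output genes rose in 16 of 19 cases and fell in 1, in both adjustments, that over all genes and that adjusted over the list alone (list adjusted p = 5.77e-08, adjusted p = 0.0925 with an estimated correlation), with PHLDA1 from 5.33 ± 3.28 to 175 ± 8.77 RPKM. Senescence hallmark genes rose in 7 of 11 cases and fell in 0, likewise when adjusted over the list alone (list adjusted p = 0.00278, adjusted p = 0.184 with an estimated correlation). By limma-voom HMGB1, HMGB2 and the cyclin CCNA2 were among the higher genes of this list, and GLB1 was lower. Matrix genes fell in 20 of 28 cases and rose in 2 (21 and 2 adjusted over the list alone, list adjusted p = 2.55e-14, adjusted p = 0.0925 with an estimated correlation), with THBS1, a matricellular glycoprotein, from 2936 ± 123 to 157 ± 23.5 RPKM. Interferon response genes fell in 20 of 23 cases and rose in 0 (21 and 0 adjusted over the list alone, list adjusted p = 3.49e-15, adjusted p = 0.160 with an estimated correlation), with IFI6 from 1139 ± 359.6 to 27.2 ± 1.38 RPKM. Of 29 lysosome genes, 9 fell and 1 rose (11 and 1 adjusted over the list alone, list adjusted p = 3.20e-05, adjusted p = 0.184 with an estimated correlation).

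Of 32 60S ribosomal protein genes 24 rose and 0 fell (26 and 0 adjusted over the list alone, list adjusted p = 6.10e-10, adjusted p = 0.0925 with an estimated correlation), and of 21 40S genes 16 rose and 0 fell (18 and 0 adjusted over the list alone, list adjusted p = 1.67e-07, adjusted p = 0.0925 with an estimated correlation). RPL23 rose from 9.47 ± 1.11 to 27.4 ± 0.429 RPKM and RPL11 from 57.1 ± 3.51 to 161 ± 7.19. Assembly factors of the 60S subunit rose in 14 of 41 cases and fell in 2 (15 and 2 adjusted over the list alone, list adjusted p = 0.0143, adjusted p = 0.184 with an estimated correlation), a list call that was lost without knockout clone 69 with 4-OHT (adjusted p = 0.101). The 40S assembly factors did not pass as a list (adjusted p = 0.0652). Of 14 snoRNA-guided modification genes, 9 rose and 1 fell, also when adjusted over the list alone (list adjusted p = 0.00162, adjusted p = 0.184 with an estimated correlation), and DKC1 rose from 3.02 ± 0.236 to 7.57 ± 0.691 RPKM. Mitosis genes rose in 15 of 33 cases and fell in 0 (18 and 0 adjusted over the list alone, list adjusted p = 3.69e-05, adjusted p = 0.184 with an estimated correlation), with UBE2C, a ubiquitin-conjugating enzyme of mitotic exit, from 0.668 ± 0.944 to 14.6 ± 5.38 RPKM and CDC20 from 9.41 ± 2.16 to 56.7 ± 6.46. Histone genes rose in 36 of 39 cases and fell in 0 (37 and 0 adjusted over the list alone, list adjusted p = 9.65e-16, adjusted p = 0.184 with an estimated correlation). Translation factors (13 of 29 higher and 1 lower; 14 and 1 adjusted over the list alone, list adjusted p = 0.00319), nuclear OXPHOS genes (15 of 24 and 0; 19 and 0 adjusted over the list alone; adjusted p = 8.46e-08) and cholesterol synthesis genes (8 of 20 and 0; 10 and 0 adjusted over the list alone; adjusted p = 2.26e-04) also passed. With an estimated correlation these lists had adjusted p of 0.184, 0.0925 and 0.0925. Lists of DNA replication (adjusted p = 0.889), RNA polymerase I (0.951), ATF4 targets (0.738), cytosolic chaperones (0.350) and chaperones of the endoplasmic reticulum (0.669) did not pass. With fry, cytosolic chaperones (adjusted p = 9.63e-04) and 40S assembly factors (0.00586) passed. All 4 mitochondrially encoded genes tested rose, and their share of reads went from 0.00338% and 0.00436% in clones 66 and 69 to 0.270% and 0.239%.

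**Figure D2:**
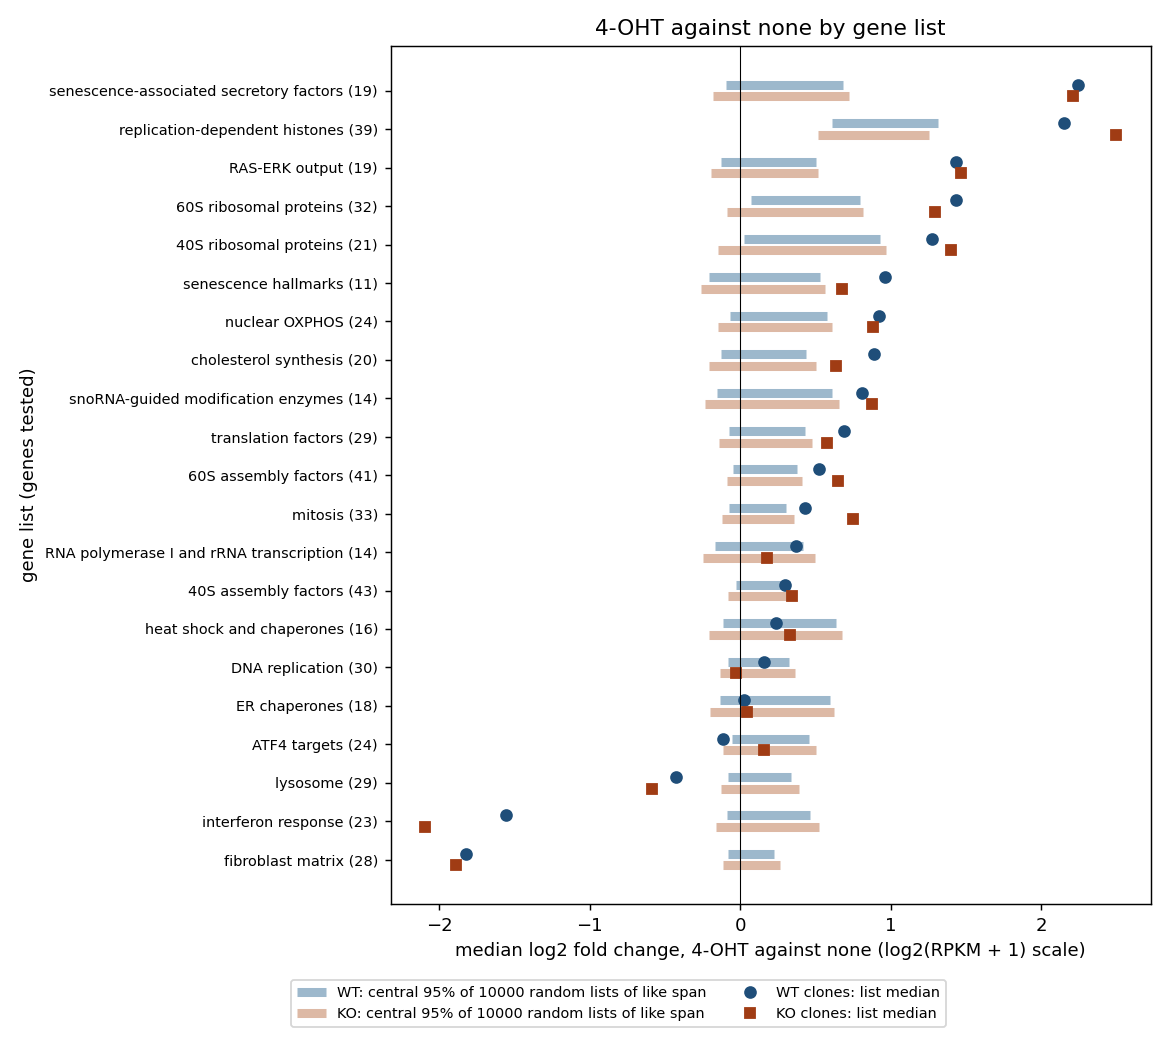
Median log2 fold change with 4-OHT against none of tested gene lists (points, WT and knockout clones; number of tested genes in brackets) on the log2(RPKM + 1) scale, with bars for the central 95% of medians of 10000 random lists matched on gene span. The fibroblast matrix list lies at -1.82 in WT and -1.89 in knockout clones, and the histone list at 2.15 and 2.50. Random lists for histones held mostly longer genes.

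Span and log2 fold change correlated here with a rho of -0.217 across genes, and 4-OHT was again confounded with any batch of the tables. The count was 1108 without knockout clone 66 and 1512 without clone 69 among the libraries without 4-OHT, 1908 without the shallow library of clone 66 with 4-OHT and 3470 without clone 69 with 4-OHT; with only the 4 knockout libraries in the fit it was 1281. Of 102 genes chosen by the rule and called here, 18, 11, 10 and 3 were not called in the 4 settings that left out a library, and 0 changed sign. Median-ratio scaling gave 1003 genes higher and 1346 lower in place of 1504 and 929.

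The next comparison asked what differs between knockout and WT clones without 4-OHT. ATF4 targets, genes of amino acid supply and the stress response, had lower footprint values in the knockout clones, with 2 of 23 members above 0 and a median log2 difference of -0.49. The list passed its test and lost that call with an estimated correlation (adjusted p = 0.672) and with fry, a rotation test of lists (0.298). PSAT1, an enzyme of serine synthesis, was at 3.76 ± 0.225 RPKM in WT and 1.47 ± 0.409 in knockout clones (mean ± SD, n = 2). PTGS2, the prostaglandin-forming enzyme COX-2, was at 10.5 ± 0.416 in WT and 59.6 ± 19.2 in knockout clones, and IGFBP2, an insulin-like growth factor binding protein, at 1.11 ± 0.596 and 8.15 ± 2.52. No single gene passed limma-trend over 8071 genes (lowest adjusted p 0.212, 684 genes at an unadjusted p under 0.05). Limma-voom on the recovered reads, a test chosen after the tables were seen, gave 33 genes higher and 29 lower. Without knockout clone 69, CCDC105 was higher and CYP2A13, ISYNA1, C9orf16 and PIGY were lower by limma-trend, and with all 8 libraries in the fit EEF1A2 and MX1 were higher and DPT lower. Of these, ISYNA1, C9orf16 and PIGY lie outside the rule for named genes and were picked after their values were seen.

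The 4 genes with the smallest p did not pass limma-trend. They were EEF1A2 (ENSG00000101210.12; GRCh38.p14 chromosome 20, 63488014 to 63499083), a translation elongation factor of muscle and nerve, PTGS2 (ENSG00000073756.12; chromosome 1, 186671791 to 186680423), BLOC1S3 (ENSG00000189114.6; chromosome 19, 45178784 to 45217083) and CYP2A13 (ENSG00000197838.4; chromosome 19, 41088451 to 41096195). EEF1A2 was at 0.513 ± 0.241 RPKM in WT and 8.10 ± 1.29 in knockout clones. On the log2(RPKM + 1) scale the difference was 2.59 ± 0.22 (SE), with an adjusted p of 0.212 by limma-trend. EEF1A2 passed in 6 of 12 alternatives (lowest adjusted p 6.46e-04), CYP2A13 in 3 of 10 and BLOC1S3 in 2 of 14. PTGS2 differed by 2.35 ± 0.25 (adjusted p = 0.274); over 14 alternative settings its adjusted p ranged from 1.25e-05 to 0.998, and 4 passed. BLOC1S3 was at 2.81 ± 0.123 in WT and 0.373 ± 0.0140 in knockout clones, and its span overlaps EXOC3L2. CYP2A13 was at 15.7 ± 0.0338 in WT and 1.16 ± 1.03 in knockout clones, and its reads can be shared with near-identical CYP2A genes. Genes that passed limma-voom included the interferon-induced GTPase MX1 (0.297 ± 0.0501 and 1.64 ± 0.176 RPKM in WT and knockout clones), the laminin chain LAMA5 (1.86 ± 0.626 and 5.80 ± 0.459), the chemokine CXCL12 (10.4 ± 6.91 and 1.66 ± 0.0725) and the hyaluronan-degrading protein CEMIP (11.4 ± 2.61 and 3.53 ± 1.21). Over 14 alternatives MX1 passed in 6 and LAMA5, CXCL12 and CEMIP in 4 each. Limma-voom fits are several of these alternatives, and none of them left out a library.

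The list test of ATF4 targets gave an adjusted p of 2.12e-08, against 0.672 with an estimated correlation. Adjusted over the list alone, 6 of its genes were lower and 0 higher; limma-voom over all genes called PSAT1, SLC7A5, ALDH1L2 and ASNS lower, ASNS passing in 3 and the others in 4 of 14 alternatives. SLC7A5, an amino acid transporter, was at 9.54 ± 0.540 RPKM in WT and 4.97 ± 0.431 in knockout clones, and ASNS, asparagine synthetase, at 5.67 ± 0.434 and 2.82 ± 1.23. Secretory factors were higher in knockout clones (median 0.31, 13 of 16 above 0, adjusted p = 0.00112, adjusted p = 0.684 with an estimated correlation), with 4 genes higher and 1 lower adjusted over the list alone. IGFBP5 was at 123 ± 1.27 RPKM in WT and 225 ± 30.9 in knockout clones, and the protease MMP3 at 8.41 ± 1.13 and 18.9 ± 4.27. Higher lists were also 60S ribosomal proteins (median 0.26, adjusted p = 0.00112), 40S ribosomal proteins (0.26, 0.00112), interferon response (0.26, 0.00121) and lysosome (0.13, 0.00235). With an estimated correlation these 4 had adjusted p of 0.684, 0.672, 0.727 and 0.727. Cholesterol synthesis (0.15, 0.0365) and histones (0.13, 0.0365) were higher as well (adjusted p = 0.684 for each with an estimated correlation). Adjusted over the list alone, the interferon and lysosome lists had 1 higher gene each and the other 4 of these 6 lists had 0. No list passed with an estimated correlation, and none with fry. CDKN1A was at 10.01 ± 5.90 RPKM in WT and 8.73 ± 2.40 in knockout clones, RPL23 at 7.74 ± 0.896 and 9.47 ± 1.11, and neither passed any setting.

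The ATF4 list passed with each of the 4 libraries left out in turn, while without knockout clone 69 the other 7 lists missed the threshold, with adjusted p from 0.0701 to 0.494. Without WT clone 15 the interferon (0.219), lysosome (0.141) and histone lists (0.209) and without WT clone 54 the cholesterol list (0.257) missed it too. With all 8 libraries in the fit the histone list missed it (0.0919). The cholesterol and histone lists also missed it by limma-voom with all 8 libraries (0.0532 and 0.104) and on CPM (0.0532 and 0.0944). IL6 was read only in the table without 4-OHT. It had 0 reads in both WT clones, where 3 reads would be 0.473 and 0.791 RPKM. In knockout clones 66 and 69 it was at 1.09 and 1.72 RPKM, about 5 and 14 reads. The matched span did not give whole numbers of reads for this gene, so these counts and floors are approximate.

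With 4-OHT, knockout and WT clones were compared to ask whether the loss of SNORA13 changes cells under treatment. Footprints on TAGLN, an actin-binding protein of contractile cells, were lower in knockout clones, at 104 ± 11.1 RPKM in WT and 27.3 ± 5.68 in knockout clones (mean ± SD, n = 2; adjusted p = 0.823). Its span overlaps PCSK7. IGFBP2 was higher, at 1.19 ± 0.449 and 8.51 ± 0.384. CDKN1A was at 151 ± 30.4 RPKM in WT and 110.1 ± 36.4 in knockout clones. No gene passed limma-trend over 7702 genes (lowest adjusted p 0.823, 365 genes at an unadjusted p under 0.05), and limma-voom gave 27 genes higher and 27 lower, or 11 and 12 with all 8 libraries in the fit.

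The 4 genes with the smallest p were TAGLN (ENSG00000149591.16; GRCh38.p14 chromosome 11, 117199294 to 117207465; log2 difference -1.90 ± 0.24, SE), IGFBP2 (2.13 ± 0.28), ADGRE1 and HIST1H2AJ (1.91 ± 0.30), each with an adjusted p of 0.823. ADGRE1 was at 0.443 ± 0.0551 RPKM in WT clones and listed at 0 in both knockout clones. It passed in 1 of 12 alternatives and HIST1H2AJ in 2 of 14. Over 14 alternatives the adjusted p of TAGLN ranged from 3.85e-10 to 1.000 and that of IGFBP2 from 3.07e-10 to 1.000; 5 passed for each. PTGS2, higher in knockout clones by limma-voom, was at 36.03 ± 9.68 RPKM in WT and 102 ± 33.97 in knockout clones. Limma-voom also gave a lower CDKN1A (log2 difference -0.65, adjusted p = 0.0268), the single setting of 14 in which that gene passed, with a highest adjusted p of 1.000. Among secretory factors limma-voom gave AREG, a ligand of the EGF receptor (13.3 ± 3.01 and 41.3 ± 3.87 RPKM in WT and knockout clones), MMP1 (1415 ± 4.23 and 2278 ± 91.5) and STC1 (366 ± 75.8 and 519 ± 48.8) higher. The matricellular proteins CCN1 (666 ± 71.99 and 433 ± 96.7) and THBS1 (229 ± 48.7 and 157 ± 23.5) were lower by the same test, THBS1, whose span overlaps FSIP1, having been higher by limma-voom without 4-OHT (2241 ± 134 and 2936 ± 123). Over 14 alternatives with 4-OHT THBS1 passed in 1, PTGS2 and AREG in 4 each and MMP1, STC1 and CCN1 in 3 each; without 4-OHT THBS1 passed in 3 of 14. MT-CO2 was at 493 ± 244 RPKM in WT and 1577 ± 239 in knockout clones and was higher by limma-voom, as were MT-ATP6 and MT-ATP8; 3 of 4 such genes passed adjusted over the list alone.

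Mitosis genes were higher in knockout clones (median 0.22, 25 of 33 above 0, adjusted p = 0.00200, adjusted p = 0.794 with an estimated correlation). Histone genes were higher too (median 0.32, 32 of 38 above 0, adjusted p = 0.00206, adjusted p = 0.831 with an estimated correlation). Adjusted over the list alone, 0 genes of either list passed by limma-trend, and limma-voom over all genes gave the histone genes HIST2H2BE and HIST1H3D higher, which passed in 1 and 3 of 14 alternatives. MKI67 was at 1.48 ± 0.0889 RPKM in WT and 3.02 ± 0.208 in knockout clones (adjusted p = 0.823), DKC1 at 5.01 ± 0.494 and 7.57 ± 0.691, and RPL23 at 27.4 ± 0.345 and 27.4 ± 0.429. ATF4 targets (median -0.06), 60S ribosomal proteins (0.20) and 40S ribosomal proteins (0.05) did not pass (adjusted p = 0.788, 0.129 and 0.106). Without WT clone 15 the histone median was -0.12 and the list missed the threshold (0.542), and without knockout clone 69 both lists missed the threshold (0.628 for mitosis and 0.639 for histones). Leaving out knockout clone 69 left the shallow library of clone 66 as the single knockout library and gave 861 genes, 251 higher and 610 lower.

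The last comparison asked whether the response to 4-OHT differs between genotypes. Mitosis genes and ATF4 targets had a higher log2 change with 4-OHT in knockout than in WT clones, and interferon response and cholesterol synthesis genes a lower one. All 4 lists passed their test, none with fry, and with an estimated correlation each had an adjusted p of 0.875. The median difference was 0.32 for mitosis (26 of 33 genes above 0, adjusted p = 0.00212) and 0.26 for ATF4 targets (16 of 24, 0.00772). It was -0.30 for interferon response (3 of 23 above 0, 0.00736) and -0.34 for cholesterol synthesis (6 of 20, 0.0249). The knockout minus WT median of ATF4 targets was -0.49 without 4-OHT and -0.06 with it. That of interferon response was 0.26 without 4-OHT and 0.04 with it, where 11 genes were tested. For these lists the interaction mostly restates the difference between genotypes without 4-OHT. Adjusted over the list alone, 1 interferon gene was lower and no gene of the other 3 lists passed. CDKN1A differed by -0.38 ± 0.59 (SE, adjusted p = 0.917). No gene passed limma-trend over 8715 genes (lowest adjusted p 0.534, 452 genes at an unadjusted p under 0.05), and limma-voom gave 1 gene higher and 3 lower. Without knockout clone 69 with 4-OHT all 4 lists missed the threshold, with adjusted p of 0.423 for mitosis, 0.732 for ATF4 targets, 0.242 for interferon response and 0.732 for cholesterol synthesis, and MCM10 (higher) and OVCA2 (lower), genes outside the rule and picked after their values were seen, passed. The interferon list also missed it without knockout clone 69 without 4-OHT (0.345) and without WT clone 15 without 4-OHT (0.354), and the cholesterol list without knockout clone 69 (0.187) or WT clone 54 (0.105) of the libraries without 4-OHT and without WT clone 15 with 4-OHT (0.147). With all libraries the interferon list missed it with a pseudocount of 0.1 (0.0597), by limma-voom (0.387, and 0.115 with the clone as a fixed block) and on CPM (0.217).

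The 4 genes with the smallest p were MX1 (-1.01 ± 0.12, SE), DPT (0.81 ± 0.12), F2RL1 (1.43 ± 0.23) and ACSS1 (0.61 ± 0.10), none of which passed. MX1 was at 0.297 ± 0.0501 RPKM in WT and 1.64 ± 0.176 in knockout clones without 4-OHT, and with 4-OHT it was listed at 0 in both WT clones. Limma-voom gave COL1A1 higher and CITED2, TAGLN and THBS1 lower in this test. CITED2, a transcriptional coregulator (ENSG00000164442.10; GRCh38.p14 chromosome 6, 139371807 to 139374648), went from 633 ± 27.4 to 153 ± 12.8 RPKM in WT and from 1123 ± 79.4 to 109 ± 17.4 in knockout clones; over 16 alternatives its adjusted p ranged from 0.00173 to 0.996, and each of these 4 genes passed in 2. COL1A1 went from 1646 ± 74.05 to 83.1 ± 8.60 in WT and from 1103 ± 169.6 to 111 ± 6.95 in knockout clones. At this number of clones simulated 4-fold changes were recovered for 10% of genes by limma-trend and 60% by limma-voom, so differences of this size can go unseen.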

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

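The weighing of a lasting difference between clones and the limma-voom test of the interaction were chosen after the results were seen. A test of the difference between genotypes in the response to 4-OHT picked out 4 lists. The median difference (knockout minus WT, log2) was 0.32 for mitosis, 0.26 for ATF4 targets, -0.30 for interferon response and -0.34 for cholesterol synthesis. For ATF4 targets and interferon response it mostly restates the difference between genotypes without 4-OHT (-0.49 and 0.26, against -0.06 and 0.04 with 4-OHT). With an estimated correlation all 4 had an adjusted p of 0.875, none passed with fry (a rotation test), the interferon list missed the threshold by limma-voom (0.387), and without knockout clone 69 with 4-OHT, the deeper of the 2 knockout libraries with 4-OHT, they had adjusted p of 0.423, 0.732, 0.242 and 0.732. By limma-voom the same test picked out CITED2 (-1.37), COL1A1 (1.05), TAGLN (-1.33) and THBS1 (-0.94), with adjusted p of 0.0137 for CITED2, COL1A1 and THBS1 and 0.0193 for TAGLN. Over 16 alternatives the adjusted p ranged from 0.00173 to 0.996 for CITED2, from 1.84e-04 to 0.996 for COL1A1, from 0.00635 to 0.996 for TAGLN and from 3.77e-04 to 0.996 for THBS1. ACSS1 moved in opposite directions in the clones of each genotype, with a difference of 0.61, and did not pass the test of that difference (adjusted p = 0.832). ZNF524, singled out after its values were seen, did so too, with a difference of -2.47 (adjusted p = 0.832). It went from 0.709 ± 0.252 to 2.63 ± 0.488 RPKM in WT and from 2.48 ± 0.895 to 0.357 ± 0.505 in knockout clones, on at most 14 reads per library.

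The lower ATF4 targets in knockout clones without 4-OHT were weighed against 3 explanations, although this list loses its call with an estimated correlation (adjusted p = 0.672) and with fry (0.298). A single clone is argued against by the 4 pairs of 1 knockout and 1 WT clone, whose medians ranged from -0.57 to -0.40. On depth, limma-voom values, which weight by depth, gave a median of -0.60, though weights cannot remove a bias from depth. The median was -0.56 for clone 66 against 15, where the knockout library was the shallower. For clone 69 against 54, where the knockout library was the deeper, it was -0.40, which argues against depth as the cause. A lasting difference between clones that is unrelated to SNORA13 stays open. With 4-OHT the median of the same list was -0.0551, against -0.49 without. It lay above -0.1, the bound set against that explanation, but the spread does not part it from -0.24, the bound set for it. The SE of 0.0993 behind this spread is over 21 genes of the list and not over clones. Loss of SNORA13 as the source of the lower values was not tested apart from such differences.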

How the results depend on the processing

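Limma-voom (except with the clone as a random block), median-ratio scaling, CPM and limma-trend with the clone as a random block were chosen after the tables were seen; the cause of the shifts below was not tested. For knockout against WT without 4-OHT (0 genes, limma-trend) the count was 3 with all 8 libraries, 3 with the clone as a random block (replicate block), 49 on CPM, 62 by limma-voom, 66 by limma-voom with all 8 libraries and 63 with the clone as a random block as well (replicate block). With 4-OHT (0 genes) it was 54 by limma-voom, 23 by limma-voom with all 8 libraries, 23 with the clone as a random block as well (replicate block) and 2 on CPM. For the interaction (0 genes) limma-voom gave 4 genes and with the clone as a fixed block (replicate block) 13. For 4-OHT in WT clones (1900 genes) limma-voom gave 2972 and with the replicate block 3051, while limma-trend with the replicate block gave 1567; in knockout clones (2433) the 4 libraries alone gave 1281 and the replicate block 2030. Leaving out 1 library, with the lone library of a group assumed to vary like the others, gave 0 to 5 genes between genotypes without 4-OHT (5 without knockout clone 69), 0 to 861 with 4-OHT (861 without knockout clone 69), 0 to 2 for the interaction (2 without knockout clone 69 with 4-OHT), 815 (without WT clone 54 without 4-OHT) to 1080 in WT and 1108 (without knockout clone 66 without 4-OHT) to 3470 (without knockout clone 69 with 4-OHT) for 4-OHT in knockout clones. The histone median between genotypes with 4-OHT ranged from -0.12 without WT clone 15 to 0.68 without WT clone 54. Of 47 list calls over the 5 comparisons, 0 held with an estimated correlation, 36 lists passed with fry (18 in each 4-OHT comparison, 0 between genotypes and 0 for the interaction) and 41 to 53 in the other settings with all libraries over all 5. Pseudocount 0.1, no filter, median-ratio scaling and no ribosomal protein and mitochondrially encoded genes moved no count between genotypes from 0, nor any 4-OHT count by more than 1.5 times. No sign of a called named gene was reversed in any setting. Knockout against WT over both treatments, TMM, RLE and DESeq2 were planned for deposited counts alone and were not run. Depth limits most the knockout library of clone 66 with 4-OHT (190878 reads).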

Other observations

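Of the tests below, those of the pseudocount, of more mitochondria and of clones that differ for other reasons, and the limma-voom tests, were chosen after the result was seen. The difference between knockout and WT clones was compared without and with 4-OHT over 7190 genes tested in both tables. The log2 differences correlated across genes, which are not independent replicates, with a Pearson r of 0.145 and a Spearman rho of 0.126. At an unadjusted p under 0.05 in both, 32 genes differed in the same direction and 5 in opposite ones, where independent lists would share 22.9 in all. By limma-voom 5 genes passed in both tables, namely BLOC1S3, IGFBP2, PTGS2, STK25 and THBS1, of which 3 had the same sign. With 4-OHT STK25 and THBS1 passed in 1 of 14 alternatives each, and without it BLOC1S3 passed in 2 of 14. IGFBP2 was at 1.11 ± 0.596 RPKM in WT and 8.15 ± 2.52 in knockout clones without 4-OHT and at 1.19 ± 0.449 and 8.51 ± 0.384 with it. PTGS2 was at 10.5 ± 0.416 and 59.6 ± 19.2 without and at 36.03 ± 9.68 and 102 ± 33.97 with 4-OHT.

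KRT10, a keratin of differentiated epidermis, rose with 4-OHT from 0.590 ± 0.359 to 6.94 ± 4.60 RPKM in WT clones and from 0.0650 ± 0.0919 to 4.04 ± 2.52 in knockout clones, while the desmosome protein DSP fell from 0.830 ± 0.0616 to 0.212 ± 0.0203 and from 0.785 ± 0.101 to 0.0565 ± 0.0799. TIE1, an endothelial receptor kinase, rose in WT clones from 0.177 ± 0.154 to 1.79 ± 1.05; in knockout clones it was listed at 0 without and at 0.812 ± 0.479 with 4-OHT (adjusted p = 0.0627) and passed in 6 of 12 alternatives, limma-voom among them. In WT clones TIE1 and KRT10 passed in 10 and DSP in 11 of 13 alternatives, and in knockout clones KRT10 passed in 9 of 12. The melanocyte, leukocyte and epithelial marker lists had 1, 3 and 2 tested genes in the 4-OHT comparisons and none was called over all genes by limma-trend. Limma-voom gave MITF lower and CD68 higher in both of these comparisons and CD14 higher in WT clones. EPB41L4A was read only in the table without 4-OHT, with 0 and 1 reads in the WT clones and 0 and 0 in the knockout clones.

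Genes with a short genomic span had higher values with 4-OHT, with a rho of span and log2 fold change of -0.28 in WT clones and a median of 2.06 for 60 genes up to 1000 bp. The pseudocount is argued against by limma-voom values, which gave a rho of -0.21. Over the 8595 genes outside the histone, ribosomal protein, OXPHOS and mitochondrially encoded lists rho was -0.26, so the trend was not confined to these lists. They are a small part of the tested genes, so leaving them out could move rho only a little. Span trends that differ from library to library stay open, since the rho of span and the difference of the 2 libraries of a group reached 0.167, above the bound of 0.141. A batch of the tables cannot be told apart from 4-OHT, so a change in which genes the cells translate and a change in library preparation may both be candidate explanations.

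The 4 mitochondrially encoded genes were higher with 4-OHT, and with 4-OHT higher in knockout clones for 3 of them adjusted over the list alone. On a short span alone, their median in WT clones lay at percentile 98.97 of 97 nuclear genes with a span under 1.5 kb. Those genes were not matched on span any closer. The median rise over all tested genes was 2.06 up to 1000 bp and 0.86 from there to 3000 bp. The 4 genes also had few reads without 4-OHT, so a short span alone stays undecided. More mitochondria were weighed by nuclear OXPHOS genes, whose upper quartile of log2 fold change was 1.40 against a bound of 2.02. That bound comes from genes with few reads without 4-OHT, and 16 of 24 nuclear OXPHOS genes rose in WT clones. The test therefore cannot decide on more mitochondria. Clones that differ for reasons other than the knockout stay open, since the gap between the WT clones was 0.601 of the gap between the genotypes in one treatment and 0.926 in the other. The shares of these genes without 4-OHT rest on few reads. Different capture of mitochondrial ribosomes in the libraries with 4-OHT is a candidate explanation that these tables do not test.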
